A study of Mus musculus with 24 samples.

How the data were processed

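Pituitary RNA from 24 mice aged 8 weeks was measured on 24 Illumina expression arrays, 1 array per sample. The labels give 4 groups of 6: wild-type males, Cga-deficient (mutant) males, wild-type females and mutant females. All were of a mixed C57Bl6j 129S2SvPas strain, and the wild types were littermates. Per the labels' protocols, total RNA was isolated with the RNAqueous 4PCR kit, DNase-treated and checked on a BioAnalyzer, and 500 ng was amplified to biotin-labelled cRNA with an Illumina TotalPrep kit.

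The deposited non-normalized table holds, per the file headers, the mean bead intensity of 45281 probes on each array, on a linear scale. It also holds the detection p-value of each probe, per the file headers the test of its signal against the array's negative controls, and the number of beads behind each deposited intensity. Signals were summarised with GenomeStudio 2011.1, per the submitters' processing notes. The bead standard errors in 24 further columns were not used. A second deposited table holds the authors' processed intensity of the same probes. Its ranks matched those of the raw intensities of the same array (rank correlation at least 0.999999), its column medians lay between 112.7 and 112.9, and it was on a linear scale and not centred. Its sorted values were nearly equal between arrays, as after quantile normalization, but the step is not given in the sources used here, and the table served only as an alternative.

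The raw intensities were background-corrected and quantile-normalized with limma 3.58.1 (function neqc, which estimates the negative controls from the detection p-values; offset 16) in R 4.3.3. A probe was kept when its detection p was under 0.05 on at least 6 arrays, which left 23133 probes. Probe names came from the platform annotation: 34885 probes had 1 gene symbol, 18 had several and 10378 had none. Of those with 1 symbol, 34807 matched a mouse gene in RefSeq. Each gene was represented by the kept probe with the highest mean over all arrays, giving 12027 genes. The 3708 kept probes without a single symbol entered no comparison. Among 4883 genes with several kept probes, probes with calls in opposite directions were found for 285 genes in males, 141 in females, 288 in the average, 25 in the difference between the sexes, 104 between wild-type sexes and 0 between mutant sexes.

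The linear model (limma, lmFit and eBayes) had 1 mean for each of the 4 groups and 1 spread shared by all. It gave 6 comparisons: mutant minus wild type in males, in females and averaged over the sexes, the difference of that effect (female minus male), and female minus male in wild types and in mutants. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 12027 genes. Unless named otherwise, adjusted p-values of genes are from this model, group values are mean log2 intensities ± SD over 6 arrays, and a log2 difference is given ± its standard error. The number of arrays limits the precision: the median standard error of a difference between groups was 0.117. No label ties samples to litters. The p-values rest on the spread between the 6 animals within a group, pooled over all 4 groups. Wide scatter in 1 group thus enters every comparison of that gene.

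The 25 gene lists were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. The lists were tested with camera (limma, preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Of 331 listed genes, 254 were measured. Where the count of members adjusted over the list alone differs from the count over all genes, both are given; elsewhere they are equal.

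The text names the pituitary hormone genes, Tceal5, Xist, Eif2s3y and Kdm5d whatever their values; Ddx3y was on that list and was not measured. It further names the 10 largest called rises and falls of each genotype comparison with no overlap between mutant and wild-type arrays, and the 6 largest called differences each way in the other comparisons. From each list it takes up to 4 members with the smallest adjusted p and members that went against the rest. A gene undetected on any array of the dimmer group is given as "at least N-fold", a form chosen after the values were seen for genes detected on some of its arrays. For the difference between the sexes, values of genes not detected on all arrays are given with each signal raised to the lowest signal of any detected probe on its array, also chosen after the values were seen. The at least N-fold bound sets the brighter group's mean against a mean over the dim group's arrays. That mean takes, on each array, the higher of the lowest signal of any detected probe and the gene's own signal. The lowest detected signal was 5.52 to 5.79 log2 in wild-type males, 5.32 to 5.46 in wild-type females and 5.11 to 5.28 in mutants. Raised signals thus differ between groups, which by itself shifts differences that rest on them.

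The alternatives were no background correction, scaling to the 75th percentile, the authors' table, no or a stricter detection filter, all probes singly, only the groups compared, another variance model (trend and robust), array weights, other thresholds, and leaving out each array. The files name no chip, so a planned fit with the chip as a block was not run. After the raw values were seen, a split by raw background was added: within each group 3 arrays had a raw 1st percentile below the group's mean and 3 above it, in every group the first 3 and the last 3 in the order of the files. The pattern is that of 2 batches, each holding 3 arrays of every group, but the files name none. It served as a block and as a split into 12 and 12 arrays.

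The model was tested on simulated data for 12027 genes with the real means and spreads, 50 genes changed at each of 4 sizes. At a log2 change of 1 it recovered 96% of changed genes for males, 96% for females, 100% for the average, 84% for the difference between the sexes, 98% for wild-type sexes and 88% for mutant sexes. At 0.5 the shares were 62%, 52%, 82%, 24%, 62% and 60%. False calls made up 2.65% to 6.67% of calls. The simulated genes varied independently and few of them changed, and the number that change sets how strict the adjusted p is. Recovery and false calls in the real comparisons can therefore differ from these shares. Between mutant sexes, where 8 genes were called, the threshold was stricter than in the simulation, so recovery there is likely lower.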

Results

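Gene expression in the pituitary gland was compared between mice lacking Cga, which encodes the alpha subunit shared by thyrotropin, luteinizing hormone and follicle-stimulating hormone, and their wild-type littermates, in both sexes at 8 weeks. Each of the 4 groups held 6 arrays. The median number of beads per probe lay between 42 and 44 on every array. The share of probes detected was 41.7% ± 1.17 (SD, n = 6) in wild-type males, 48.2% ± 0.86 in mutant males, 45.1% ± 0.89 in wild-type females and 48.9% ± 1.37 in mutant females. The SD of the background signal averaged 19.0 in wild-type males against 10.3 to 11.3 in the other groups. Each array correlated with the mean of the rest of its group at 0.988 to 0.995, and no pair of arrays was identical. The leading principal component held 57.5% of the variance and parted the genotypes (mean scores -36.8 and -31.9 in wild-type males and females, 32.8 and 35.9 in mutants). The next, with 11.4%, parted wild-type males (-20.5) from wild-type females (22.0), while both mutant groups lay near 0 (-0.80 and -0.75).

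Cga itself was 5.14-fold lower in mutant males (12.41 ± 0.16 against 14.77 ± 0.09, n = 6 each; adjusted p = 3.8e-16) and 4.28-fold lower in mutant females (12.68 ± 0.27 against 14.78 ± 0.10; adjusted p = 4.0e-15). It stayed detected on all 12 mutant arrays. Whether its probe lies in the deleted part is not given in the sources used here, so the level checks the labels only as far as it parts the groups. Tshb, the beta subunit of thyrotropin, rose 1.41-fold in males (adjusted p = 0.00029) and 2.12-fold in females (adjusted p = 3.2e-09). Lhb, the beta subunit of luteinizing hormone, fell 2.32-fold in males (adjusted p = 8.8e-09) and 1.48-fold in females (adjusted p = 0.00054). Fshb, the beta subunit of follicle-stimulating hormone, rose 4.32-fold in females, from 8.68 ± 1.2 to 10.79 ± 0.28 (adjusted p = 1.3e-05), and in males measured 11.65 ± 0.36 in wild types and 11.22 ± 0.29 in mutants (adjusted p = 0.30). That male p-value rests on the spread shared by all 4 groups, which the scatter of wild-type females widened. Prl, prolactin, fell 1.42-fold in females (adjusted p = 0.0067), with a log2 difference of -0.10 ± 0.15 in males (adjusted p = 0.59). Gh, growth hormone, fell 1.13-fold in females (adjusted p = 0.026) and differed by -0.15 ± 0.06 in males (adjusted p = 0.053). The female call of Gh was lost without wild-type female 1, mutant female 2 or mutant female 6, and when only the 2 female groups were fitted (adjusted p = 0.085). Its male difference passed under 6 other settings, such as the authors' table (adjusted p = 0.018). Pomc, the precursor of corticotropin, differed by 0.03 ± 0.08 in males and 0.06 ± 0.08 in females (adjusted p = 0.77 and 0.56). The probes of Gh, Prl, Pomc and Tshb, and that of Cga in wild types, lay near the top of the signal range, where folds can be compressed. Lhb came close to it in wild-type males (up to 14.29), while the group means of Fshb, 8.68 to 11.65, lay below it.

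**Figure D1:**
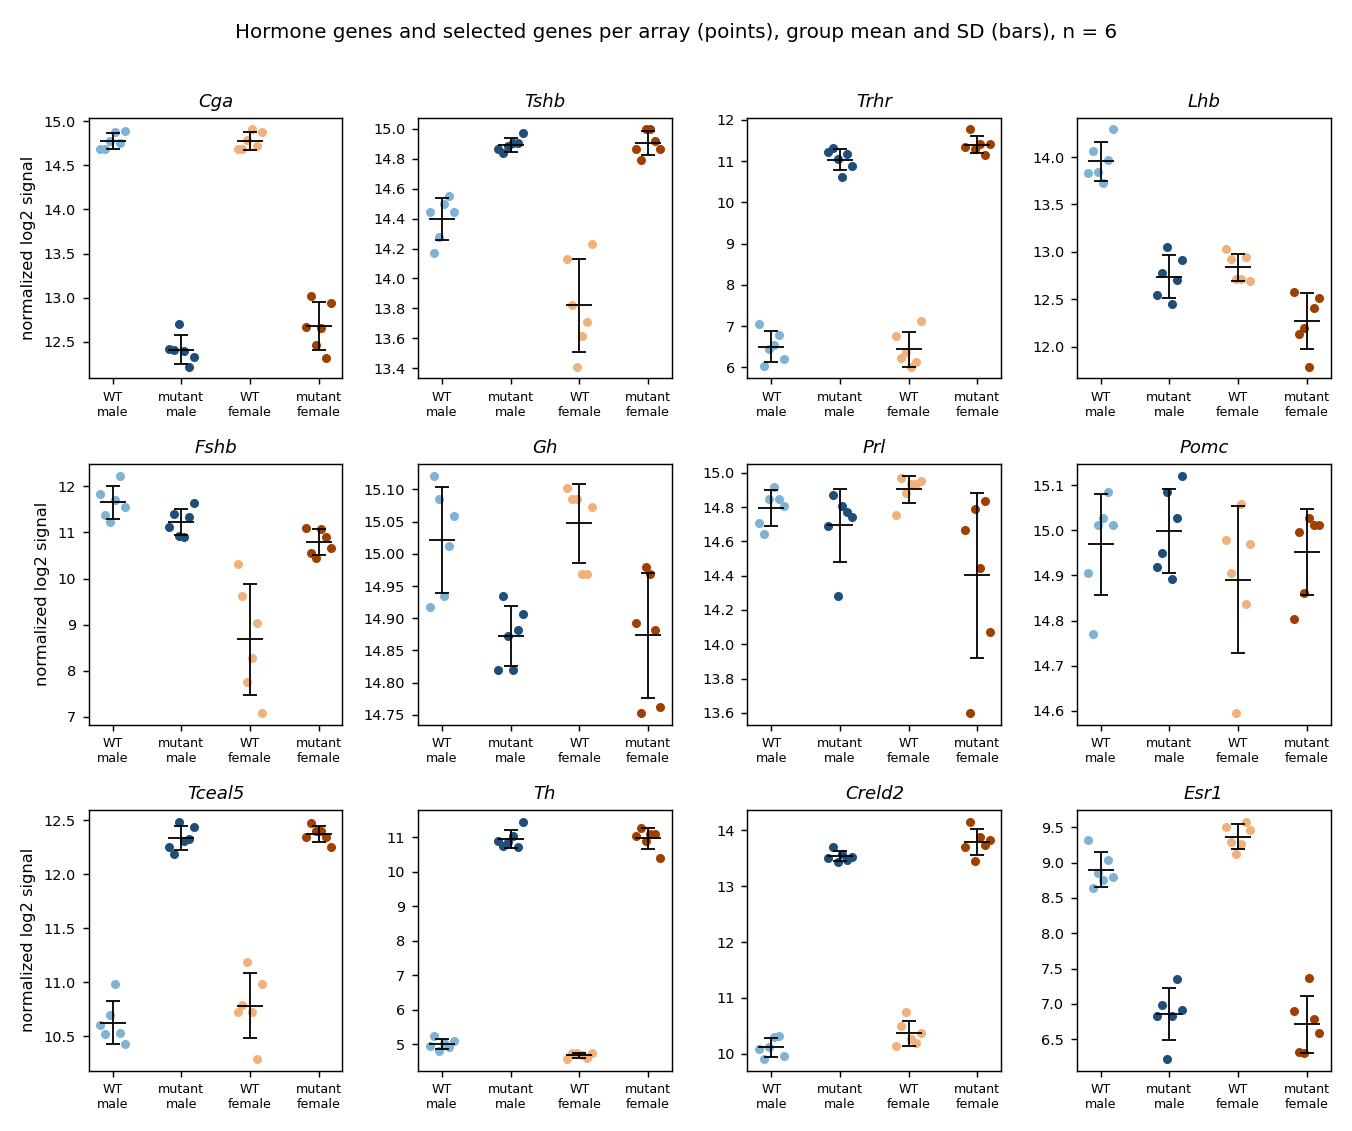
Log2 intensity (vertical axes) of Cga, the pituitary hormone genes, Tceal5, Trhr, Th, Creld2 and Esr1 on each of the 24 arrays, by group; points are arrays, and the bars give the mean and SD of 6. Cga separates the genotypes in both sexes, Tshb is higher in mutants of both sexes, and Fshb is low and scattered in wild-type females (8.68 ± 1.2).

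In mutant males, the largest rises were those of Wfdc17 (at least 170-fold; adjusted p = 3.6e-19) and Wfdc18 (at least 66.0-fold), which encode small secreted proteins with a whey acidic protein domain. Th, the rate-limiting enzyme of catecholamine synthesis, rose at least 39.9-fold, Calb2, the calcium-binding protein calretinin, at least 35.7-fold, and Sst, somatostatin, at least 13.5-fold. Tyrp1, an enzyme of melanin synthesis (at least 20.2-fold), Ly6g6c (at least 19.6-fold), Nupr1, a stress-induced nuclear protein (24.7-fold), and Derl3, a component of endoplasmic reticulum-associated degradation (at least 17.8-fold), rose as well. The largest falls were those of Dock3 (48.4-fold lower; log2 -5.60 ± 0.38, adjusted p = 4.3e-12), Mc5r, a melanocortin receptor (at least 40.8-fold lower), and Neurog1, a neurogenic transcription factor (at least 24.2-fold lower). Mc5r was detected on 3 and Neurog1 on 4 of the 6 mutant arrays. Ush1c (18.6-fold), Agtr1a, an angiotensin II receptor (18.4-fold), Cntnap4 (12.1-fold), Fut2, a fucosyltransferase (at least 11-fold), Galnt16 (11.1-fold), Gpr83 (at least 9.38-fold) and Greb1, an estrogen-induced gene (at least 8.43-fold), were lower too.

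The 8 measured thyrotrope markers all rose in mutant males (camera, adjusted p = 0.00015; adjusted p = 0.032 with an estimated correlation). Among them were Trhr, the receptor for thyrotropin-releasing hormone (23.1-fold), Dio2, the deiodinase that activates thyroxine (8.40-fold), and the transcription factor Isl1 (2.39-fold). Of 20 genes of endoplasmic reticulum stress and protein folding, 17 rose and 1 fell (adjusted p = 1.8e-09; adjusted p = 0.032 with an estimated correlation), with Creld2 10.7-fold, Sdf2l1 8.90-fold and the disulfide isomerase Pdia4 4.68-fold higher, and the stress transcription factor Atf4 falling by 0.25 log2. The call of Atf4 was lost under 75th percentile scaling (adjusted p = 0.36) and on leaving out any of 6 arrays. Of 16 secretory granule genes, 10 rose and 1 fell (2 fell adjusted over the list alone; adjusted p = 0.0024, and adjusted p = 0.042 with an estimated correlation), including the granule peptide precursor Vgf (6.18-fold) and Ptprn (2.89-fold), with Cadps, a priming factor of granule release, falling by 0.37 log2. All 10 immune cell markers rose (adjusted p = 1.2e-06; adjusted p = 0.15 with an estimated correlation), such as the antigen presentation genes H2-Aa (4.05-fold) and Cd74 (3.18-fold) and the macrophage gene Aif1 (3.04-fold). Of 12 genes of the TCEA and TCEAL/BEX family, 7 rose and 0 fell (adjusted p = 0.020; adjusted p = 0.20 with an estimated correlation). Tceal5, a transcription elongation factor A-like gene of the kind the series title refers to, rose 3.27-fold in males, from 10.63 ± 0.20 to 12.34 ± 0.11 (adjusted p = 1.7e-12).

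The lists of lactotrope and somatotrope markers went down in mutant males. Their hormone genes Prl and Gh, with probes near the top of the signal range, were not called in males over all genes (above). Of 5 lactotrope markers 3 fell (4 adjusted over the list alone; adjusted p = 0.0035, and adjusted p = 0.15 with an estimated correlation), with Angpt1, an angiopoietin, 5.26-fold and Esr1, estrogen receptor alpha, 4.13-fold lower. Of 6 somatotrope markers 4 fell (5 adjusted over the list alone) and 1 rose (adjusted p = 0.049; adjusted p = 0.26 with an estimated correlation). Neurod4, a neurogenic transcription factor, was 5.38-fold, Ghrhr, the receptor for growth hormone-releasing hormone, 2.91-fold and Ghsr, the ghrelin receptor, at least 2.51-fold lower, while Dlk1, an imprinted gene, rose (adjusted p = 1.2e-05) and a second Dlk1 probe gave -0.16 (adjusted p = 0.070). The Dlk1 probe used lay at the top of the signal range (14.74 in wild-type and 15.18 in mutant males), so the size of its rise is uncertain. This list's call was also lost with the authors' table (adjusted p = 0.060), with raw background as a block (adjusted p = 0.051) and on leaving out any of 13 single arrays.

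The remaining lists did not pass the test in males. Members of most were called, but so were 51.5% of all 12027 genes, which stands beside each count of members. Gonadotrope markers had 0 of 8 higher and 4 lower (1 and 4 adjusted over the list alone; camera adjusted p = 0.25), among them Gnrhr, the receptor for gonadotropin-releasing hormone (2.70-fold lower). Thyroid hormone responsive genes had 2 of 8 higher and 3 lower (2 and 4 adjusted over the list alone; adjusted p = 0.25), with the corepressor Hr 5.82-fold and Klf9 2.24-fold lower. Sex steroid responsive genes had 1 of 11 higher and 4 lower (adjusted p = 0.25), and neuropeptides 4 of 12 higher and 2 lower (adjusted p = 0.25), with Tac1, the substance P precursor, at least 7.57-fold and Cartpt 7.64-fold higher and Penk, preproenkephalin, at least 2.25-fold lower. Of 19 cell cycle genes 7 rose and 1 fell (adjusted p = 0.18), with Birc5 (survivin) at least 1.80-fold higher. Cyclins and cell cycle inhibitors had 4 of 17 higher and 6 lower (adjusted p = 0.81; mean above and median below 0), with the G1 regulators Ccne1 at least 2.29-fold, E2f1 3.09-fold and Cdkn1c 3.27-fold higher. The inhibitor Cdkn2c was 1.68-fold lower. Immediate early and heat shock genes had 6 of 14 higher and 3 lower (adjusted p = 0.56), with Fos 8.32-fold higher. Higher and lower members numbered 7 and 4 of 14 growth factors and receptors (adjusted p = 0.56), 4 and 2 of 14 pituitary transcription factors (adjusted p = 0.56), 4 and 2 of 13 pituitary tumour genes (adjusted p = 0.79), and 0 and 3 of 13 cholesterol synthesis genes (adjusted p = 0.56). They numbered 5 and 2 of 11 endothelial markers (adjusted p = 0.58), 3 and 3 of 11 fibroblast and pericyte markers (3 and 4 adjusted over the list alone; adjusted p = 0.81), and 2 and 2 of 10 folliculostellate and stem cell markers (adjusted p = 0.79). Corticotrope and melanotrope markers had 1 and 1 of 5 (1 and 2 adjusted over the list alone; adjusted p = 0.89) and posterior lobe markers 1 and 1 of 8 (adjusted p = 0.81; mean below and median above 0), with Oxt, oxytocin, 3.38-fold lower. Of 7 sex chromosome genes 1 was lower (0 adjusted over the list alone; adjusted p = 0.59), Eif2s3y at -0.28 log2, of which a second probe gave 0.32. Limma called none of the 3 red blood cell markers, with Hba-a1 and Alas2 at -0.62 and -0.84 log2 (adjusted p = 0.081 and 0.098; list adjusted p = 0.58).

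In all, 6197 of 12027 genes were called in males, 3005 higher and 3192 lower in mutants, and 1154 of them changed at least 2-fold, 629 higher and 525 lower. The 6 arrays of each genotype did not overlap for 30.7% of genes, against 0.216% by chance. Among the 12 arrays of lower raw background 4014 genes were called and among the other 12 arrays 4073, of which 3076 were shared with the same direction. The wild-type male arrays had the highest background spread of the groups (above), which stands beside each male difference.

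**Figure D2:**
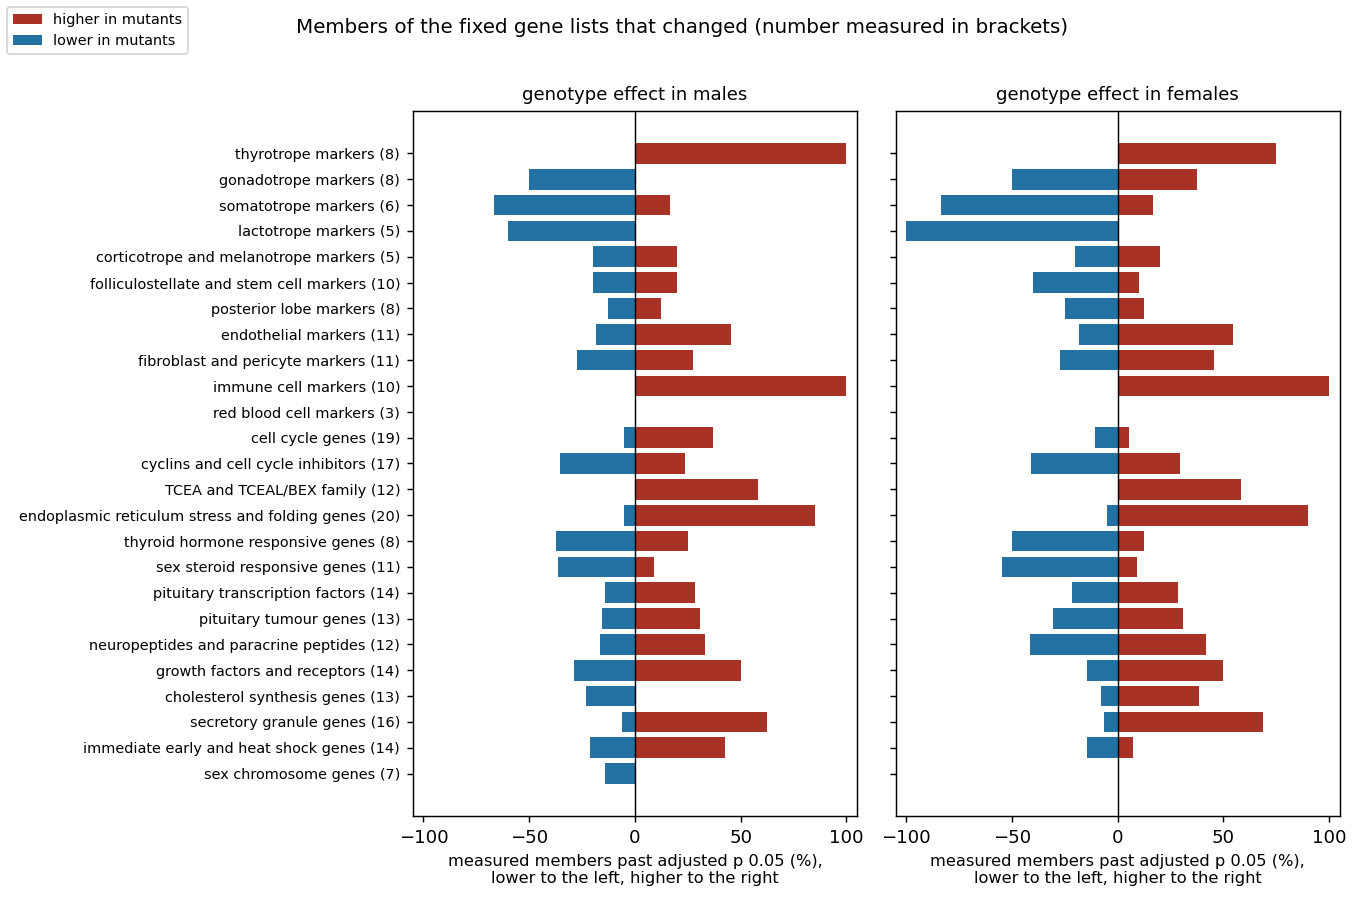
Percentage of the measured members of each gene list (rows; number measured in brackets) called higher (red, right) or lower (blue, left) in mutants, for males and females. All 10 immune cell markers and most of the 20 endoplasmic reticulum genes (17 in males, 18 in females) are higher, and lactotrope markers extend only to the left.

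In mutant females the largest rises were largely those of the males: Wfdc17 at least 211-fold (adjusted p = 1.2e-19), Wfdc18 at least 95.5-fold, Th at least 47.5-fold, Calb2 at least 44.7-fold, Nupr1 37.5-fold, Trhr 31.0-fold, Ly6g6c at least 26.3-fold, Tyrp1 at least 19.7-fold and Sst at least 15-fold. Dgkk, a diacylglycerol kinase, rose 32.4-fold in females. The largest falls were those of Reln, the extracellular matrix protein reelin (at least 170-fold lower; adjusted p = 1.9e-21), and Crhbp, the binding protein of corticotropin-releasing hormone (at least 164-fold lower; adjusted p = 2.6e-14). They were detected on 2 and 5 of the 6 mutant female arrays. Dock3 (68.6-fold), Ecel1, an endothelin-converting enzyme-like protease (38.7-fold), Greb1 (at least 36.0-fold), Mc5r (at least 21.9-fold, detected on 1 of 6 mutant arrays), Smco2 (at least 14.3-fold, detected on 1 of 6), Gal, the peptide galanin (18.9-fold), Neurod4 (16.9-fold) and Kctd4 (at least 15.3-fold) were lower as well.

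Of 8 thyrotrope markers 6 rose in mutant females (camera, adjusted p = 5.9e-05; adjusted p = 0.013 with an estimated correlation), including Dio2 (7.64-fold) and the transcription factors Gata2 (4.62-fold) and Isl1 (3.02-fold). Genes of endoplasmic reticulum stress and folding rose for 18 of 20 (adjusted p = 7.0e-13; adjusted p = 0.0090 with an estimated correlation), with Creld2 10.7-fold and Sdf2l1 6.54-fold higher. The 1 member that fell was Xbp1, a transcription factor of the unfolded protein response (by 0.41 log2, adjusted p = 0.0017), and 1 did not pass the threshold. Of 16 secretory granule genes 11 rose and 1, Pcsk1n, fell by 0.39 log2 (list adjusted p = 6.0e-05; adjusted p = 0.0090 with an estimated correlation), with Vgf 6.99-fold higher. All 10 immune cell markers rose (adjusted p = 0.00014; adjusted p = 0.24 with an estimated correlation), such as the complement gene C1qc (1.92-fold) and the macrophage receptor Csf1r (1.91-fold). All 5 lactotrope markers fell (adjusted p = 0.00027; adjusted p = 0.054 with an estimated correlation), with Angpt1 13.1-fold, Esr1 6.32-fold and Agtr1a 6.13-fold lower. Sex steroid responsive genes fell for 6 of 11 and rose for 1, Igfbp3, at 2.11-fold (adjusted p = 0.035; adjusted p = 0.22 with an estimated correlation), among them Greb1, Gal and Pgr, the progesterone receptor (at least 2.38-fold lower). That call was lost under 75th percentile scaling (adjusted p = 0.053).

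Tceal5 rose 3.01-fold in females, from 10.78 ± 0.30 to 12.37 ± 0.07 (adjusted p = 8.1e-12), and the TCEA and TCEAL/BEX family had 7 of 12 members higher and 0 lower, with the list not past the threshold (adjusted p = 0.064). Somatotrope markers had 1 of 6 higher and 5 lower (adjusted p = 0.13), thyroid hormone responsive genes 1 of 8 higher and 4 lower (5 adjusted over the list alone; adjusted p = 0.12), with Hr 3.10-fold lower, and growth factors and receptors 7 of 14 higher and 2 lower (adjusted p = 0.11), with Pdgfa 2.52-fold higher and Egf 2.11-fold lower. Gonadotrope markers went both ways, 3 of 8 higher and 4 lower (adjusted p = 0.84), with Gnrhr 3.13-fold lower and Fshb higher. Neuropeptides were called in both directions, 5 of 12 higher and 5 lower (adjusted p = 0.95; mean and median below 0, camera upward), with Tac1 at least 12.5-fold and Cartpt 11.7-fold higher. Endothelial markers had 6 of 11 higher and 2 lower (adjusted p = 0.11), fibroblast and pericyte markers 5 of 11 and 3 (adjusted p = 0.75), cholesterol synthesis genes 5 of 13 and 1 (adjusted p = 0.55), pituitary transcription factors 4 of 14 and 3 (adjusted p = 0.83; mean below and median above 0), and pituitary tumour genes 4 of 13 and 4 (5 and 4 adjusted over the list alone; adjusted p = 0.61). Cyclins and cell cycle inhibitors had 5 of 17 higher and 7 lower (adjusted p = 0.98; mean above and median below 0), with Ccne1 at least 2.92-fold and E2f1 3.34-fold higher. Cell cycle genes had 1 of 19 higher and 2 lower (0 and 0 adjusted over the list alone; adjusted p = 0.73). Folliculostellate and stem cell markers had 1 of 10 higher and 4 lower (adjusted p = 0.56), posterior lobe markers 1 of 8 and 2 (adjusted p = 0.65), with Oxt 5.50-fold lower, corticotrope and melanotrope markers 1 of 5 and 1 (adjusted p = 0.98), and immediate early and heat shock genes 1 of 14 and 2 (1 and 1 adjusted over the list alone; adjusted p = 0.95). Of the 3 red blood cell markers and 7 sex chromosome genes limma called 0 (list adjusted p = 0.69 and 0.98), with Hba-a1 at 0.28 and Eif2s3y at 0.01 log2 (adjusted p = 0.46 and 0.96).

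In all, 5808 genes (48.3% of those tested) were called in females, 2738 higher and 3070 lower (2402 and 3517 under 75th percentile scaling). Of the 5808, 965 changed at least 2-fold, 580 higher and 385 lower. The share of 48.3% stands beside each count of list members in females. The groups did not overlap for 23.6% of genes (0.216% by chance). Within the arrays of lower and higher raw background the counts were 3611 and 3676, with 2591 shared in direction.

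Averaged over the sexes, 7242 genes were called, 3374 higher and 3868 lower in mutants, and 976 changed at least 2-fold, 553 higher and 423 lower. Next to genes already named, Spint4, a Kunitz-type protease inhibitor gene, was at least 8.99-fold higher in males and at least 12.9-fold in females, while Pcsk6, a proprotein convertase, was 11.3-fold lower on average and the kallikrein gene Klk1b27 at least 9.76-fold lower in males and at least 13.4-fold in females. Of the genes called in males and in females, 1953 were higher in both (684 if the lists were independent), 1926 were lower in both (815 if independent), and 132 were called in opposite directions. Both sets of calls use the same spread for each gene, so genes of small spread tend to be called in both. Independence is therefore too low a baseline. Across genes, which are not independent replicates, the male and female effects correlated at r = 0.80 (Spearman 0.71); they share no array. The lists that passed on average were those of thyrotrope markers (adjusted p = 4.5e-05; 7 of 8 higher), endoplasmic reticulum genes (adjusted p = 1.5e-10), secretory granule genes (adjusted p = 0.00019), immune cell markers (adjusted p = 6.1e-06), the TCEA and TCEAL/BEX family (adjusted p = 0.020) and, downward, lactotrope markers (adjusted p = 0.0014). With an estimated correlation the adjusted p was 0.013 for each of the thyrotrope, endoplasmic reticulum and secretory granule lists, 0.19 for immune, 0.20 for TCEAL/BEX and 0.10 for lactotrope markers. Within the arrays of lower and higher raw background 5402 and 5429 genes were called, 4339 of them shared in direction.

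The genotype effect differed between the sexes most in Crhbp and Reln. Crhbp and Reln, which dropped so far in females, lay near the detection floor in males (detected on 2 and 1 of 6 wild-type and 3 and 0 of 6 mutant arrays; adjusted p = 0.57 and 0.37). With signals raised to that floor, the effects differed by -7.30 and -6.98 log2 (adjusted p of the model without the floor, 9.3e-10 and 9.9e-17). Gal (-4.25), Crtac1 (-3.02) and, with the floor, Rxfp1, a relaxin receptor (-2.50), and Rnase1, a secreted ribonuclease (-2.03), also had effects further downward in females. In the other direction, Fshb (2.54 ± 0.48, adjusted p = 0.00090), Ramp1, a receptor activity-modifying protein (2.26), and Dgkk (2.01) had effects further upward in females. So had, with the floor, the dopamine receptor Drd4 (2.02), Cabp2, a calcium-binding protein (1.99), and Spink8 (1.84). Drd4 fell at least 4.65-fold in males and was undetected in wild-type and mutant females. The rise of Tshb was larger in females by 0.59 ± 0.15 log2 (adjusted p = 0.0091) and the fall of Lhb was smaller by 0.65 ± 0.18 (adjusted p = 0.016); under 75th percentile scaling both lost the call (adjusted p = 0.12 and 0.093). Tshb lay near the top of the signal range in both mutant groups (14.89 and 14.90), so that its difference rests on the wild-type levels (14.40 and 13.82) and a further rise in either sex can be hidden. For Tceal5 the effects differed by -0.12 ± 0.16 (adjusted p = 0.65). Of 10 immune cell markers 4 (5 adjusted over the list alone) had a smaller rise in females, such as Cd74 (-0.93 ± 0.21, adjusted p = 0.0038), and this was the only list of 25 past the threshold here (camera, adjusted p = 0.014; adjusted p = 0.61 with an estimated correlation). Its call was also lost within the 12 arrays of lower raw background (adjusted p = 0.37). In all 1637 genes were called, 872 with a difference above 0 and 765 below; 75th percentile scaling turned the split to 733 and 961, and of differences of at least 1 log2 130 lay above and 151 below 0. Within the arrays of lower and higher raw background the counts were 185 and 311.

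Between wild-type females and males, the largest differences were again in Crhbp and Reln. By construction, the difference of the genotype effect equals the sex difference of mutants minus that of wild types. Genes shared by these comparisons are therefore not separate evidence. Crhbp was at least 152-fold (adjusted p = 1.8e-13) and Reln at least 135-fold higher in females (adjusted p = 3.9e-21). They were detected on 2 and 1 of the 6 wild-type male arrays. They were followed by Xist, the X inactivation transcript (at least 12.9-fold), Gal (15.4-fold), Rxfp1 (at least 5.53-fold) and Rnase1 (at least 3.98-fold, detected on 5 of 6 female arrays). Males were higher in the Y-linked genes Eif2s3y (at least 21.2-fold) and Kdm5d (at least 3.58-fold), and in Fshb (7.84-fold), Lcn2, the iron-sequestering protein lipocalin 2 (5.13-fold), Drd4 (at least 4.13-fold) and Grem1, an antagonist of bone morphogenetic proteins (at least 3.90-fold). Xist was detected on every wild-type female array and no male array, and Eif2s3y and Kdm5d on every male and no female array. Cell cycle genes were higher in females for 11 of 19 and lower for 0 (12 and 0 adjusted over the list alone; camera, adjusted p = 0.0028; adjusted p = 0.61 with an estimated correlation), with Birc5 at least 1.86-fold, Mcm3 at least 1.17-fold and Bub1b 1.59-fold higher, genes of mitosis and DNA replication. No other list passed (lowest adjusted p = 0.14, gonadotrope markers, 0 of 8 higher and 3 lower in females). In all 3288 genes were called, 1506 higher and 1782 lower in females, 263 of them at least 2-fold; under 75th percentile scaling the split was 1858 and 1440. The groups did not overlap for 11.1% of genes (0.216% by chance). The wild-type male arrays had a wider background (mean SD 19.0 against 11.3 in wild-type females) and fewer probes detected (41.7% against 45.1%). That stands beside each of these differences, also that of Birc5, which was detected on 4 of 6 wild-type male arrays. Among 6 wild-type arrays of lower raw background and 6 of higher raw background, with the mutants in the fit, 1409 and 979 genes were called, 618 shared in direction.

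**Figure D3:**
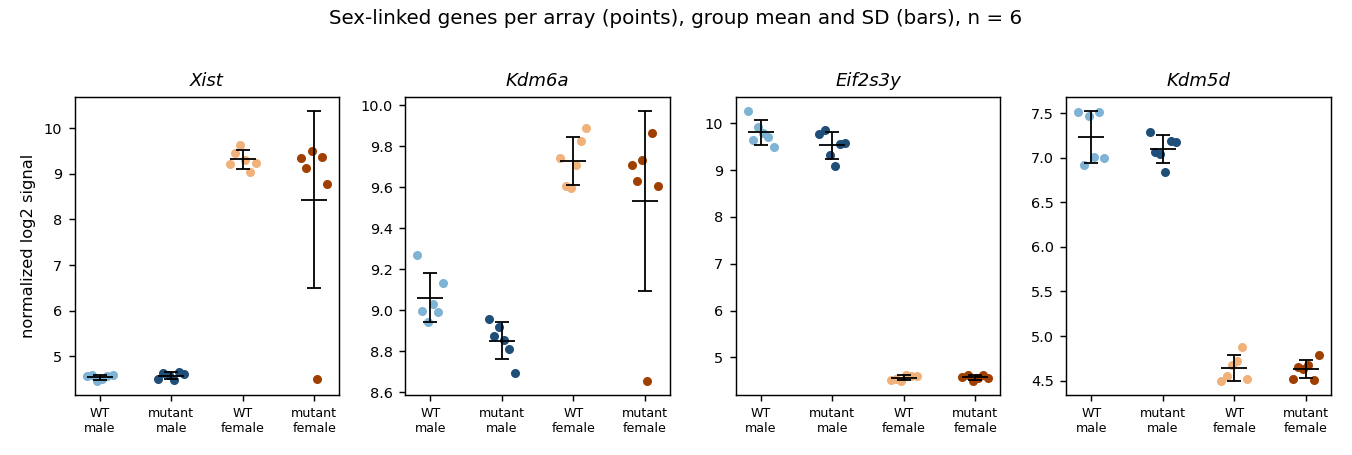
Log2 intensity (vertical axes) of Xist, the X-linked Kdm6a and the Y-linked Eif2s3y and Kdm5d on each array, by group, with points for arrays and bars for the mean and SD of 6. One mutant female array, number 4, lies at the male level for Xist and Kdm6a, and the Y-linked genes stay at the female level on it.

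Between mutant females and males only 8 genes were called, and 5 of them lie on the sex chromosomes. Xist was at least 9.26-fold higher in females (at least 16-fold without mutant female 4, which lacked its signal). The X-linked Kdm6a, a histone demethylase, was 1.60-fold higher in females, while Eif2s3y (at least 20.1-fold), Kdm5d (at least 3.74-fold) and Uty (1.80-fold) were higher in males. The other 3 were Defb50, a beta-defensin (at least 1.75-fold higher in females, adjusted p = 0.0032), Hapln4, a hyaluronan link protein (3.68-fold higher in females, adjusted p = 0.041), and Aox3, an aldehyde oxidase (1.82-fold higher in males, adjusted p = 0.0094). Crhbp and Reln, so different between wild-type sexes, lay near the detection floor in mutants (detected on 3 and 0 of 6 male and 5 and 2 of 6 female arrays; adjusted p = 0.998 and 0.84). Fshb differed by -0.43 ± 0.34 (adjusted p = 0.85), with the wide scatter of wild-type females included in its standard error. Tshb measured 14.89 ± 0.05 and 14.90 ± 0.08 in mutant males and females. Of the 3288 genes called between wild-type sexes, 5 were called between mutant sexes and 1571 had the same sign; their median absolute log2 difference was 0.47 in wild types and 0.091 in mutants. Across all genes the sex differences of wild types and mutants, which share no array, correlated at r = 0.05 (Spearman -0.07).

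With the preset correlation, camera placed 5 lists past the threshold between mutant sexes: endoplasmic reticulum genes (adjusted p = 4.5e-08) and cell cycle genes (adjusted p = 0.00037) higher in females, and immune cell markers (adjusted p = 6.1e-05), folliculostellate and stem cell markers (adjusted p = 0.00051) and neuropeptides (adjusted p = 0.048) lower. For immune cell markers camera turned upward within the arrays of lower raw background (mean -0.0141, adjusted p = 0.89). None of the 5 held with an estimated correlation (adjusted p = 0.087, 0.41, 0.36, 0.35 and 0.29), and limma called none of their members over all genes, such as Creld2 (0.26 ± 0.11) and Cd74 (-0.45 ± 0.15); adjusted over the list alone, 1, 0, 1, 3 and 1 were called. Xist was undetected on mutant female 4. Without that array 9 genes were called, among them Eif2s3x and Pbdc1, named here after their values were seen. Hapln4 lost its call on leaving out any of 13 of the 24 arrays, mutant female 4 included. Kdm6a lost its call for 21 of the 24, all but wild-type males 1 and 3 and mutant female 4. Aox3, Defb50, Eif2s3y, Kdm5d, Uty and Xist were called whichever array was left out; with only the 2 mutant groups in the fit 2 genes were called, and Xist, Defb50, Aox3 and Uty were not (adjusted p = 0.11, 0.17, 0.12 and 0.13). At an unadjusted p under 0.05 there were 748 genes. The groups did not overlap for 0.258% of genes, against 0.216% by chance. Within the arrays of lower and higher raw background 4 and 3 genes were called.

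**Figure D4:**
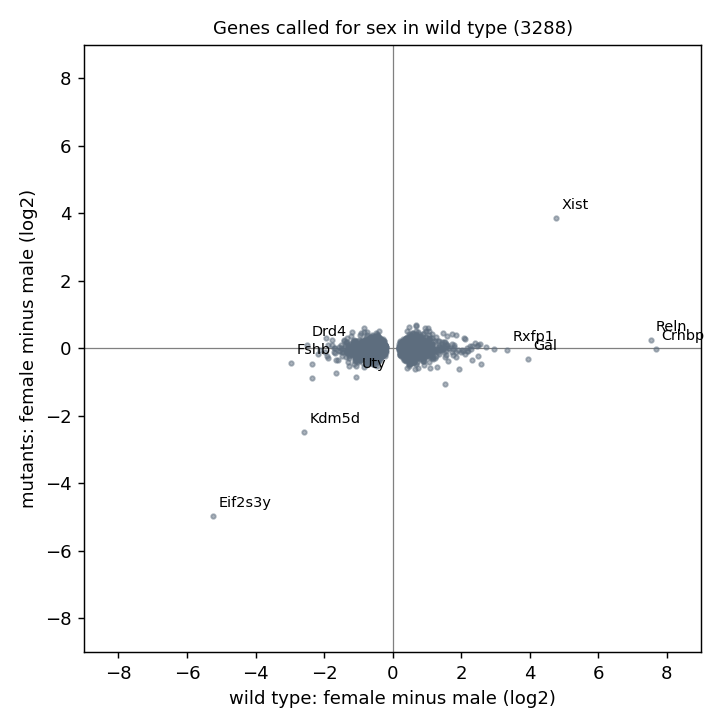
Log2 difference between females and males for each of the 3288 genes called between wild-type sexes (points), in wild types (horizontal) and in mutants (vertical). The median absolute difference is 0.47 in wild types and 0.091 in mutants; Xist, Eif2s3y and Kdm5d lie near the diagonal.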

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

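The values with signals raised to the detection floor and the tests of the spread ratio, the Y-linked genes, the Xist probes, the X-linked genes and the thyrotrope share were chosen after the results were seen; the tests of bright genes, held-out arrays, the neural list (save Gfap, whose value had been seen) and the other splits were set before their own results, but after the main comparisons had been seen.

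The effect of genotype differed between females and males for 1637 genes, by the test of the difference itself. Female minus male, the log2 differences were 2.62 for Drd4, 2.54 for Fshb, 2.26 for Ramp1, 2.10 for Spink8, 2.01 for Dgkk, 2.0 for Cabp2, -7.70 for Crhbp, -7.27 for Reln, -4.25 for Gal, -3.39 for Rxfp1, -3.02 for Crtac1, -3.00 for Rnase1, 0.59 for Tshb and 0.65 for Lhb. These are fitted values, and 6 of the genes were undetected on many arrays. Drd4 was detected only on wild-type male arrays and Rxfp1 only on wild-type female arrays. With signals raised to the detection floor the 6 gave 2.02 for Drd4, 1.84 for Spink8, -7.30 for Crhbp, -6.98 for Reln, -2.50 for Rxfp1 and -2.03 for Rnase1. On mutant male 3, Prl stood apart from the other 5 (gap 0.692 of the group's range), and on mutant female 4 Xist did (gap 0.859). Of 72 groups checked for such gaps 2 were found, where chance gives 3.6. That number does not weigh the size of a gap: Xist measured 4.49 on mutant female 4, against 8.79 to 9.49 on the other 5. Outside the genes, 2076 kept probes without a single gene symbol were called in the average comparison.

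Other splits of the same arrays were counted, 100 per comparison with the real one, and 1, the real split, gave as many genes each time. The real counts and the highest of the other splits were 6197 and 3851 in males, 5808 and 3254 in females, 7242 and 2793 for the average, 1637 and 4 for the difference between the sexes, 3288 and 463 for wild-type sexes and 8 and 6 for mutant sexes, so none of the other 99 reached the real count, by a narrow margin for mutant sexes. For mutant sexes 16 other splits called at least 1 gene. The split of a comparison's arrays by raw background called 0 genes with limma in males, in females and between the sexes of either genotype. Each side of that split held 3 arrays of each compared group, so a real difference between the groups widened the spread. The count of 0 therefore does not show that raw background had no effect. The same widening lowers, in part, the counts of the other mixed splits.

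The sex difference of the wild types was nearly absent in the mutants. A larger spread among mutant arrays could not remove calls in mutants alone, because the model gives both sex comparisons the same spread for each gene. The median standard error was 0.117 in both. The ratio of the median SD within groups was 1.0 for mutants over wild types. The background of the wild-type male arrays is argued against as the whole cause by bright genes: of 2494 genes with a mean log2 of at least 10, 23.5% were called between wild-type sexes and 0 between mutant sexes. Selection of genes on the same wild-type arrays is argued against by held-out arrays. Genes chosen on the arrays of lower raw background kept a median signed difference of 0.60 on the others, against -0.016 in mutants. Those chosen on the arrays of higher raw background kept 0.73, against 0.035. The means of these medians were 0.66 and 0.0094. A loss of sex-dependent expression with Cga is a hypothesis that stays open, and which hormone or cell type would carry it was not tested.

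Mutant female 4 had no Xist signal. Male RNA on that array is argued against by Y-linked genes: 0 of 3 reached the lowest mutant male. A failed Xist measurement is argued against because 4 of 4 Xist probes were undetected and Kdm6a lay at 8.65, below the other mutant females (9.60 to 9.87). A single X chromosome may account for it, since 4 X-linked genes that can escape inactivation lay at a median 1.03 of the way from the other mutant females to the mutant males; the shares were 1.23 for Kdm6a, 1.17 for Kdm5c, 0.89 for Eif2s3x and -0.99 for Ddx3x, which went the other way. This was found and tested on the same array, and the chromosomes themselves were not analysed here.

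Th, Calb2, Sst, Cartpt and Tac1, genes also used by neurons, rose together in mutants of both sexes. Neural tissue left on the dissected mutant glands was tested with a neural list of 24 genes: among the 13 measured, 3 were called higher and 5 lower, with a median fitted change of 0.0057 log2 (SD 0.68), or -0.15 (SD 0.59) with signals raised to the detection floor. The floor lay lower on mutant arrays (5.11 to 5.28) than on wild-type arrays (5.32 to 5.79), which by itself lowers the change of undetected genes. The -0.15 is the value of Mobp, whose fitted change was 0.089. Ghrh, undetected on all wild-type and detected on all mutant arrays, gave 0.90 fitted and 0.04 with the floor. Of the 8 detected on all arrays Nefm rose by 0.91 and Aqp4 by 0.76, while Slc17a6 fell by 0.82, Gad2 by 0.74 and Mbp by 0.47 (median -0.073, SD 0.65). By the rule set beforehand, the fitted median of 0.0057 with 3 of 13 called higher counts against neural tissue. The members went both ways, however, and the spread of the 8 is wider than the median rise of 0.5 set as the sign. This limit was not part of that rule, and with it the list does not decide the question. A larger share of thyrotropes could contribute, as the thyrotrope list rose by a median of 1.11 log2, but in whole glands a change in cell numbers and a change per cell cannot be told apart.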

How the results depend on the processing

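The raw background split was chosen after the data were seen; all other alternatives were planned. The chip as a block was not run because the files name no chip. No paired analysis was possible because the labels give no number that links animals across groups. Testing all probes singly tests more features and called 11536 probes in males, 10359 in females, 13315 on average, 3470 for the difference between the sexes, 6595 for wild-type sexes and 15 for mutant sexes. At least 2-fold changes numbered 1154, 965, 976, 281, 263 and 4. An adjusted p under 0.01 left 691 for the difference between the sexes and 1890 for wild-type sexes. With fewer arrays, those of lower raw background called 4014, 3611, 185, 1409 and 4 (males, females, difference, wild-type sexes, mutant sexes), and those of higher raw background 4073, 3676, 311, 979 and 3. Between mutant sexes 3 genes were called without background correction and 2 with only those groups fitted; the cause of the first was not tested. Gene list shifts numbered 26 of 150, 9 with an estimated correlation and 58 with fry, which asks another question. All other alternatives kept these counts within 1.5 times.

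Leaving out 1 array gave 5799 to 6291 genes in males, 5374 to 5845 in females, 7068 to 7278 on average, 1331 to 1884 for the difference between the sexes, 2808 to 3380 for wild-type sexes, 6 to 9 for mutant sexes, and 25 to 29 list shifts. Reversed values were Prkar1a between wild-type sexes under 75th percentile scaling (0.0286, adjusted p = 0.81) and the immune list between mutant sexes within the arrays of lower raw background (-0.0141, adjusted p = 0.89, camera upward); the causes were not tested. With raw background as a block the 6 counts were 6277, 5881, 7330, 1748, 3366 and 9. Of 485 calls of named genes, 145 were lost within the arrays of lower raw background and 124 within those of higher raw background (fewer arrays), 23 under 75th percentile scaling, 19 with no filter, 12 without background correction, 10 with the other variance model, 7 with the authors' table, 5 with array weights, 3 with all probes and 0 with the block; 17 of 306 were lost with only the groups compared. Of 26 list calls 17 were lost with an estimated correlation. The scalings moved the median of all genes by under 0.05 log2. Signal over background limits the dimmest genes: folds of named genes undetected on any array of the dimmer group are bounds.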

Other observations

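The test of the mutant level against the wild-type sexes was set before its result was seen; the neighbours of Cga were looked at after their values were seen.

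Around Cga on chromosome 4, 56 of the 100 nearest tested genes were called in the average comparison, against 60.2% of all genes, and 10 changed at least 2-fold, against 8.12% of all. Strain sequence near the deleted gene can differ between mutants and wild types; other window sizes had been looked at, so this is a description.

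One hypothesis was that mutants of both sexes rest at the wild-type male level. Of the genes called between wild-type sexes, 37.5% had a mutant mean nearer to wild-type males. At least 60% had been set as the sign of it, so that sign was not met. The share was 44.4% among genes higher in wild-type females and 31.6% among those higher in wild-type males, and for 35.3% the mutant mean lay between the wild-type levels. For the others it lay outside them, so a mean nearer to one sex does not place the mutants at the level of that sex. The share therefore does not decide the question. The wild-type male arrays also had the widest background (mean SD 19.0), which was not allowed for here.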
